A study of Mus musculus with 2 samples.

How the data were processed

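Gene expression was measured on 2 Affymetrix arrays, each hybridised with biotin-labelled cRNA prepared from 1 µg of total RNA. The cells came from otocysts (the epithelial vesicles that form the inner ear) of mouse embryos at embryonic day 10.5, heterozygous for an ETAR-EGFP transgene. Per the labels' protocols, the otocysts were dissociated with 0.25% trypsin, propidium iodide was added, and otocyst cells, which the labels call epithelial, were sorted by EGFP fluorescence. One array holds EGFP-positive cells and 1 holds EGFP-negative cells. How many embryos were pooled is not given in the sources used here.

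The deposited values are intensities, 1 MAS5 signal per probe set for 45101 probe sets, on a linear scale. MAS5, version 5.0, is named in the submitters' processing notes. MAS5 condenses the probe pairs of a probe set into 1 signal and scales each array by a constant. In both columns the mean after trimming the lowest and highest 2% of values was 100.0, so the 2 arrays had been brought to a common level. The scaling target, detection calls and scanner images were not used here. The direction of the values is not in doubt, since each column is 1 array and was not divided by the other or centred per gene.

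Probe sets were named from the platform's annotation, with gene identifiers looked up in the GRCm38.p6 RefSeq gene table. Of the 45101 probe sets, 34958 named 1 gene, 932 named several and were not used for naming, and 9211 were unnamed here. No coordinates are given because no genome build is attached to the signals. Some genes of interest are not reported here.

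Each array's 40th percentile of signal was taken as a floor, which was 10.4 in the EGFP-positive library and 12.4 in the EGFP-negative library. For comparison, the highest of 27 probe sets for bacterial transcripts without evident signal reached 12.3 and 9.0. The floor of the EGFP-positive library thus lies below its highest control, and for genes with an EGFP-positive signal at or below that control the signals are printed in place of a fold. List medians and counts keep the floor. Each gene was represented by its probe set with the highest mean signal over both arrays. The log2 ratio is that of EGFP-positive over EGFP-negative, with each signal raised to its array's floor. A ratio with 1 side at the floor is a lower bound and is written as "at least". Genes at the floor in both libraries were left out. A gene was counted as higher when its ratio was 2-fold or more, a log2 difference of 1.

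With 1 array per population there is no replicate, and a difference between the arrays cannot be set against a spread between samples. No p-value is given and every statement describes these 2 libraries. The number of arrays limits the precision. A partial measure of technical error was taken from genes with 2 or more probe sets above the floor in both libraries. The SD of the log2 ratio between probe sets of 1 gene was 0.315 over 5638 genes. It was 0.397 where the mean signal was under 50, 0.316 between 50 and 200, and 0.222 above 200. This SD does not include variation between embryos, sorts or hybridisations.

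Before the data were examined, 28 gene lists with 468 entries were fixed, covering otocyst regions, other cell types, signalling pathways, cell states and checks. Of these entries, 33 could not be tied to a probe set naming the gene alone and were not analysed here. Each list was summarised by the median log2 ratio of its measured members, with bounds at their bound. Its percentile was taken among 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile. The error given with a list median is the SD of 2000 bootstrap draws of its members. Genes named in the text were chosen by a rule also fixed in advance. It took the 12 highest and 12 lowest ratios among genes above the floor in both libraries and the 6 largest bounds in each direction. It added members of the region lists that differed at least 2-fold, with up to 4 further bright members, and up to 4 members of each other list with the largest ratio. It also took the 2 endothelin receptor genes, of which 1 was not analysed here. The lists of mesenchyme, endothelium, blood and neural genes hold markers of other cell types, and whether such cells carry EGFP was not tested.

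The procedure was tested on simulated data, in which 200 genes were changed between 2 arrays drawn from the real mean signals with a log2 noise SD of 0.25 per array. Over 12911 genes, 40 of 50 genes raised by 1.5 and 47 of 50 lowered by 1.5 on the log2 scale passed the 2-fold limit. All 50 genes passed at 2.5 in each direction, and 48 of 12711 unchanged genes passed. All 20 simulated lists with 8 of 15 members raised stood apart, as did 1 of 40 unchanged lists. The simulation gave every probe set the same noise and held no shift shared by the genes of a cell type. Its rates therefore do not carry over to the percentiles of the real lists. Alternatives tried were other scalings (array median, quantile, loess), floors at the 25th and 60th percentile, a pseudocount, the mean of all probe sets, leaving out probe sets that end in _s_at or _x_at, leaving out bounds, and limits of 1.5-fold and 3-fold. A floor at the 75th percentile and centring on control or epithelial probe sets were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.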

Results

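The transcriptomes of 2 cell populations sorted from the mouse otocyst at E10.5 were compared. Per the labels, EGFP from the transgene marks mainly the ventral and dorsomedial otocyst and is absent from the dorsolateral part, so the comparison asks which genes distinguish these territories. Each population was measured once, on 1 array of 45101 probe sets. The median signal was 17.6 in the EGFP-positive and 20.6 in the EGFP-negative library, and the highest signals were 7984 and 7166. Above the floor lay 12410 genes in the EGFP-positive and 12633 in the EGFP-negative library. The Spearman correlation of the 2 arrays across probe sets was 0.927. The 3' to 5' signal ratio of the Actb control was 1.34 in the EGFP-positive and 1.22 in the EGFP-negative library, and that of the Gapdh control was 0.819 and 0.849.

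EGFP-positive cells had higher signals for genes of the ventral otocyst and of epithelium, and EGFP-negative cells had higher signals for genes of mesenchyme, blood, endothelium and neural tissue. Of 13362 genes above the floor in at least 1 library, 388 were at least 2-fold higher in EGFP-positive cells and 1019 were at least 2-fold higher in EGFP-negative cells. The remaining 11955 genes, 89.5%, differed by less than 2-fold. At 4-fold the counts were 37 and 338, and at 16-fold they were 1 and 35. Among 602 genes past 2-fold with several probe sets above the floor, all probe sets went the same way for 526. Of 66 genes past 2-fold that the naming rule took and that have several probe sets, 29 had a probe set that was not past 2-fold the same way. These counts depended on the floor, with 237 and 478 genes when it was set at the 60th percentile. The split between directions depended on scaling, with 503 and 822 genes after quantile normalization, 225 and 1442 after centring on hybridisation controls, and 19 and 10706 after centring on epithelial genes, the last 2 settings being added after seeing the data.

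**Figure D1:**
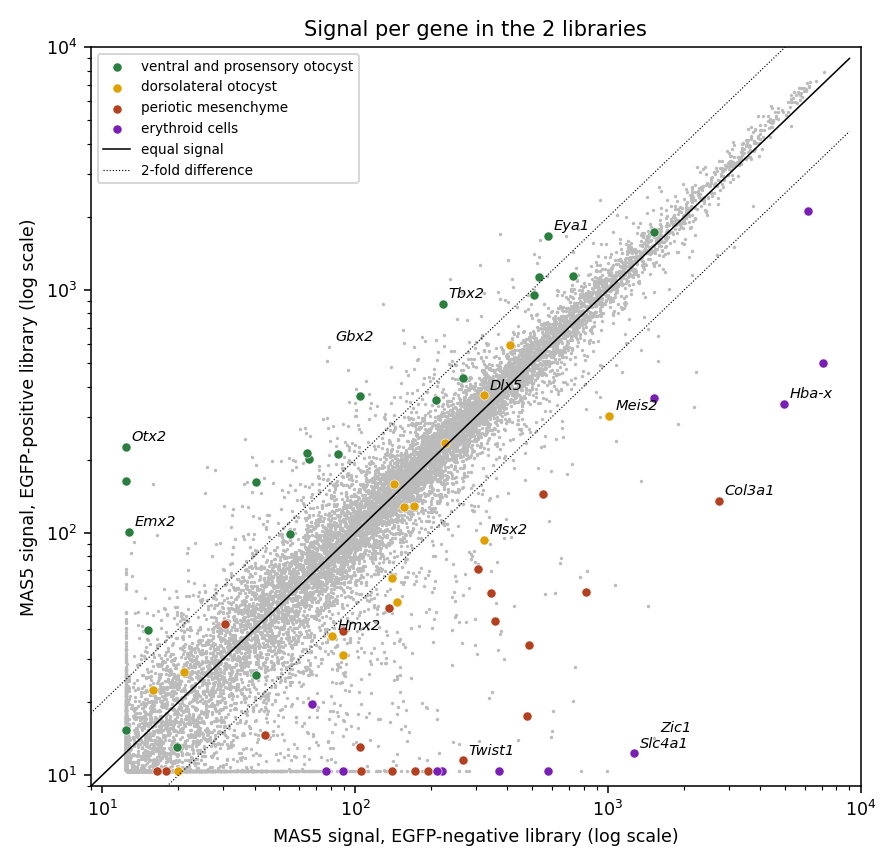
Each point is 1 of 13362 genes, with its MAS5 signal in the EGFP-negative library on the x axis and in the EGFP-positive library on the y axis, both logarithmic and raised to the floor. Coloured points are 4 preset lists. Ventral genes such as Otx2 lie above the diagonal, and erythroid and mesenchymal genes such as Slc4a1 and Col3a1 lie far below it.

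Among genes above the floor in both libraries, the 12 with the highest ratios in EGFP-positive cells included 2 homeobox transcription factors of regional identity. Gbx2, a dorsomedial otocyst marker, had a signal of 580.3 against 79.1, 7.34-fold higher. Emx2 had 100.5 against 12.7, 7.91-fold higher with the lower signal next to the floor. Espn, which encodes an actin-bundling protein of stereocilia, was 6.89-fold higher, with its lower signal, 13.3, also next to the floor. Cldn22, a tight junction claudin, was 7.22-fold higher. The retinoid receptor gene Rxrg was 5.90-fold higher and Cnmd, which encodes chondromodulin, was 6.80-fold higher at a signal of 878.3. Fam107a, Prr15, Klhl14, Tnk1 and 4930426D05Rik were 5.70-fold to 6.63-fold higher. Cemip had the highest ratio, 9.99-fold, but its other probe set had a log2 ratio of -0.07, and that of Prr15 was at 0.95. The largest bounds were those of Otx2 and Otx1, homeobox genes of the ventral otocyst, at least 18.2-fold and at least 13.1-fold higher. The signals were 225.5 and 162.9 in EGFP-positive cells against 3.2 and 0.6. Rgs13, a regulator of G protein signalling, was at least 8.05-fold higher, and Dleu7, Rhbdf2 and Cldn10 were at least 5.73-fold, 5.56-fold and 5.44-fold higher.

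The ventral and prosensory list had a median log2 ratio of 1.30 ± 0.29 (bootstrap SD, 21 genes), above all of the 10000 random lists. Of its 21 measured members, 12 were at least 2-fold higher in EGFP-positive cells and none was at least 2-fold higher in EGFP-negative cells. Besides Otx1, Otx2 and Emx2, these were Bdnf, a neurotrophin, 3.99-fold higher, Tbx2 3.96-fold, Eya4 3.47-fold, Rspo2 3.31-fold, Gata3 3.08-fold, Eya1 2.88-fold, Fgf10 2.64-fold, the Notch modulator Lfng 2.47-fold and the Notch ligand Jag1 2.13-fold. The lowest probe sets of Rspo2, Bdnf and Eya4 had log2 ratios of -0.10, 0.88 and 0.95. Sox2, a prosensory transcription factor, was 1.57-fold higher, within the 2-fold limit, and Nr2f1 was 1.14-fold higher. Genes of epithelium in general were higher too. The general otic epithelium list had a median of 1.30 ± 0.19 (17 genes), with 12 members at least 2-fold higher in EGFP-positive cells and none at least 2-fold higher in EGFP-negative cells. A list of 28 further epithelial genes, drawn up after seeing the data, had a median of 1.35 ± 0.16. The ventral median differed from that of this epithelial list by -0.047 ± 0.32.

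Within the general otic epithelium list, the adhesion gene Epcam was 2.99-fold higher in EGFP-positive cells and Cdh1, which encodes E-cadherin, 2.47-fold. Cldn6 was 3.32-fold, Cldn7 2.88-fold, Krt8 2.56-fold, Krt18 2.45-fold and the splicing regulator Esrp1 2.66-fold higher. Among otic genes, Fbxo2 was 3.42-fold, Lmx1a 3.29-fold, Sox10 2.20-fold and Pax8 2.07-fold higher. The lowest probe sets of Epcam and Sox10 had log2 ratios of 0.50 and 0.67. Bright members within 2-fold were Tbx1 (1.47-fold) and Sox9 (1.40-fold), both higher in EGFP-positive cells. Oc90, which encodes the otoconial protein otoconin-90, had a signal of 939.8 in EGFP-positive and 1405.7 in EGFP-negative cells.

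**Figure D2:**
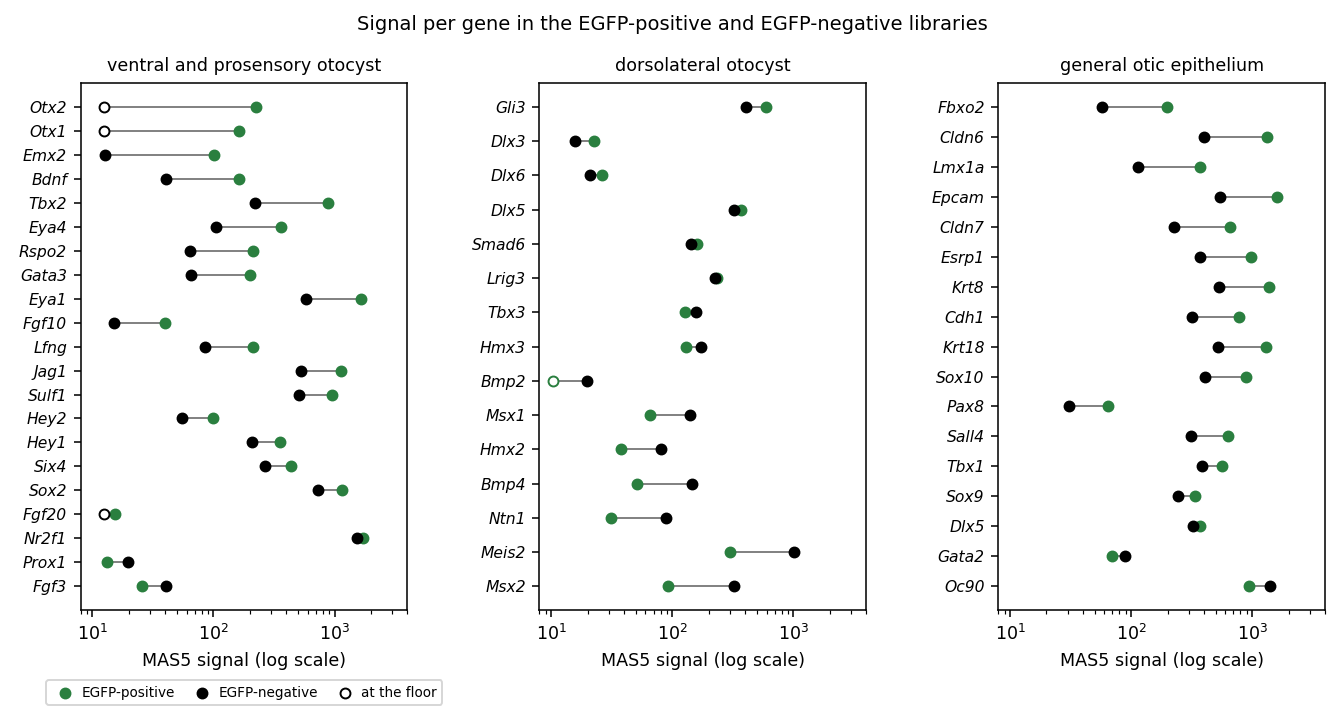
MAS5 signals (x axis, logarithmic) of the measured members of 3 lists (y axis, sorted by ratio) in the EGFP-positive library (green) and the EGFP-negative library (black), with open circles at the floor. Most ventral and general epithelial genes are higher in green, with list medians of 1.30 each, whereas 6 dorsolateral genes are at least 2-fold higher in black.

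The dorsolateral list had a median log2 ratio of -0.41 ± 0.47 (15 genes), at percentile 0.1 of random lists. Of its members, 6 were at least 2-fold higher in EGFP-negative cells, 9 were within 2-fold and none was at least 2-fold higher in EGFP-positive cells. The 6 genes were Msx2 (3.47-fold), Meis2 (3.35-fold), Ntn1 (2.86-fold), the growth factor gene Bmp4 (2.85-fold), Hmx2, a homeobox gene of vestibular development (2.16-fold), and Msx1 (2.15-fold). All 4 probe sets of Meis2 went the same way, with log2 ratios from -1.84 to -1.33, whereas the second probe sets of Msx2, Msx1 and Ntn1 were at -0.47, -0.82 and -0.06. Dlx5 had signals of 367.6 in EGFP-positive and 322.2 in EGFP-negative cells. Lrig3, Smad6 and Gli3 were 1.03-fold, 1.12-fold and 1.45-fold higher in EGFP-positive cells. Markers of other cell types were higher in the same library, with a median of -3.02 for periotic mesenchyme.

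The dorsomedial list did not stand apart, with a median of -0.06 ± 0.79 (10 genes) at percentile 37.8. Without its 3 members at the floor in 1 library, the median was 0.54 at percentile 99.85, and the list then stood apart as higher in EGFP-positive cells. This setting left out Pax3 and Wnt3a because they were at the floor in EGFP-positive cells. The shift towards EGFP-positive cells is thus built into it. Members of the dorsomedial list diverged. Gbx2 and the Wnt-responsive gene Sp5 (2.62-fold) were higher in EGFP-positive cells, whereas Pax3 (89.7 against 1.8), Fgfr3 (5.73-fold), Lef1 (3.37-fold) and Wnt3a (26.6 against 9.5) were higher in EGFP-negative cells. Wnt6 was 1.60-fold and Sp8 1.45-fold higher in EGFP-positive cells, and Axin2, a target of Wnt signalling, was 1.16-fold higher in EGFP-negative cells. The second probe set of Wnt6 had a log2 ratio of 1.45. Markers of hindbrain and of neural crest, with medians of -2.42 and -1.86, were higher in the same library as Pax3, Fgfr3, Lef1 and Wnt3a. Whether RNA of other cells raised these 4 genes was not tested.

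Genes of otic neurogenesis also diverged. The list median was -0.47 ± 0.27 (25 genes), below all of the 10000 random lists, with 3 genes at least 2-fold higher in EGFP-positive cells, 6 at least 2-fold higher in EGFP-negative cells and 16 within 2-fold. The 3 were Shox2 (2.37-fold), Pou4f1, a sensory neuron transcription factor (2.24-fold), and Neurog1, the proneural gene of the cochleovestibular ganglion (2.20-fold). Neurod1, which acts after Neurog1, was 1.98-fold higher in the same cells at a signal of 1432.4, and its second probe set had a log2 ratio of 1.44. The 6 higher in EGFP-negative cells were Ebf2 (4.93-fold), Neurod4 (39.1 against 2.6), Ebf1 (2.93-fold), the Notch ligand gene Dll3 (170.0 against 67.9), Myt1 (2.35-fold) and Ebf3 (2.11-fold). The least different probe sets of Neurog1, Pou4f1, Ebf1 and Ebf3 had log2 ratios of 0.46, 0.62, -0.50 and -0.93. Isl1, Cdkn1c and Hes6 were 1.52-fold, 1.65-fold and 1.66-fold higher in EGFP-positive cells. Markers of hindbrain, with a median of -2.42, were higher in the same library as the Ebf genes.

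Most markers of other cell types were higher in the EGFP-negative library. The periotic mesenchyme list had a median log2 ratio of -3.02 ± 0.59, with 17 of 20 measured members at least 2-fold higher in EGFP-negative cells. The erythroid list had a median of -3.84 ± 0.59, with all 12 measured members past 2-fold. Globin transcripts were bright in both libraries, with Hbb-y, named after its values were seen, at 2121 in EGFP-positive and 6191 in EGFP-negative cells. The leukocyte list stood at -2.67 ± 0.25 with all 16 members past 2-fold, endothelium at -2.06 ± 0.28 with 14 of 16, hindbrain neuroepithelium at -2.42 ± 0.52 with 11 of 15, and neural crest and glia at -1.86 ± 0.82 with 8 of 13. In the other direction, 1 hindbrain member (Irx3) and 2 neural crest members were at least 2-fold higher in EGFP-positive cells. The latter were Sox10, also an otic gene, and the neuregulin receptor gene Erbb3 (1405 against 511.1), Irx3 and Erbb3 being named after their values were seen. Each of these 6 medians lay below all random lists. The surface ectoderm list was at -0.02 ± 0.67, at percentile 51.2, with 3 members at least 2-fold higher in EGFP-positive and 2 in EGFP-negative cells, but stood apart in 2 of 9 other settings, with a median of 0.60 where the floor was at the 60th percentile or bounds were left out. Among these lists, many members were at the floor in EGFP-positive cells, 10 of 16 for endothelium and 10 of 16 for leukocytes, so that the size of these medians depends on the floor. With the floor at the 60th percentile they were -2.69 for erythroid cells, -2.24 for mesenchyme, -1.11 for leukocytes, -1.02 for endothelium and -0.99 for hindbrain, and without bounds the neural crest median was -0.69, with all 6 lists still apart from random lists.

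Of the 1019 genes at least 2-fold higher in EGFP-negative cells, 80 were in the preset lists of other cell types. Of the 12 lowest ratios, 6 were those of list members, namely Zic1, Slc4a1, Fabp7, Csf1r, Prrx1 and Twist1. Zic1, a transcription factor of dorsal neural tissue and mesenchyme, had a signal of 1523.2 in EGFP-negative against 14.2 in EGFP-positive cells, 107-fold higher. Slc4a1, the erythrocyte anion exchanger, had 1262 against 12.3, which is no higher than the highest bacterial control. The glial and neural progenitor gene Fabp7 was 39.6-fold, the macrophage receptor gene Csf1r 33.2-fold, and the mesenchymal regulator gene Prrx1 27.4-fold higher. Twist1, another mesenchymal regulator, had 266.5 against 11.5, below that control. The matrix genes Col5a2 and Nid1 were 41.4-fold and 31.5-fold higher, the sphingosine phosphate receptor gene S1pr3 was 36.0-fold higher, and Igf1 and Marveld1 were 26.5-fold and 22.4-fold higher. Plagl1 was 29.1-fold higher, but 1 of its 3 probe sets had a log2 ratio of 0.09. The least different of the 3 probe sets each of Csf1r and Marveld1 were at -0.59 and -0.70. For S1pr3, Nid1 and Slc4a1 the least different probe sets were past 2-fold too, at -2.53, -2.72 and -2.46. The largest bounds were those of Aplnr, an endothelial and mesodermal receptor gene (994.0 against 8.9), the erythroid genes Hemgn (779.5 against 5.5), Alas2 (576.5 against 5.9) and Klf1 (371.3 against 5.6), then Blvrb (281.4 against 3.1) and Emilin1 (274.3 against 7.8). Most denominators lay close to the floor, so the size of these ratios is less certain than their direction. Col3a1, a fibrillar collagen gene, was well above the floor in both libraries, at 2733 against 135.5, 20.2-fold higher.

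**Figure D3:**
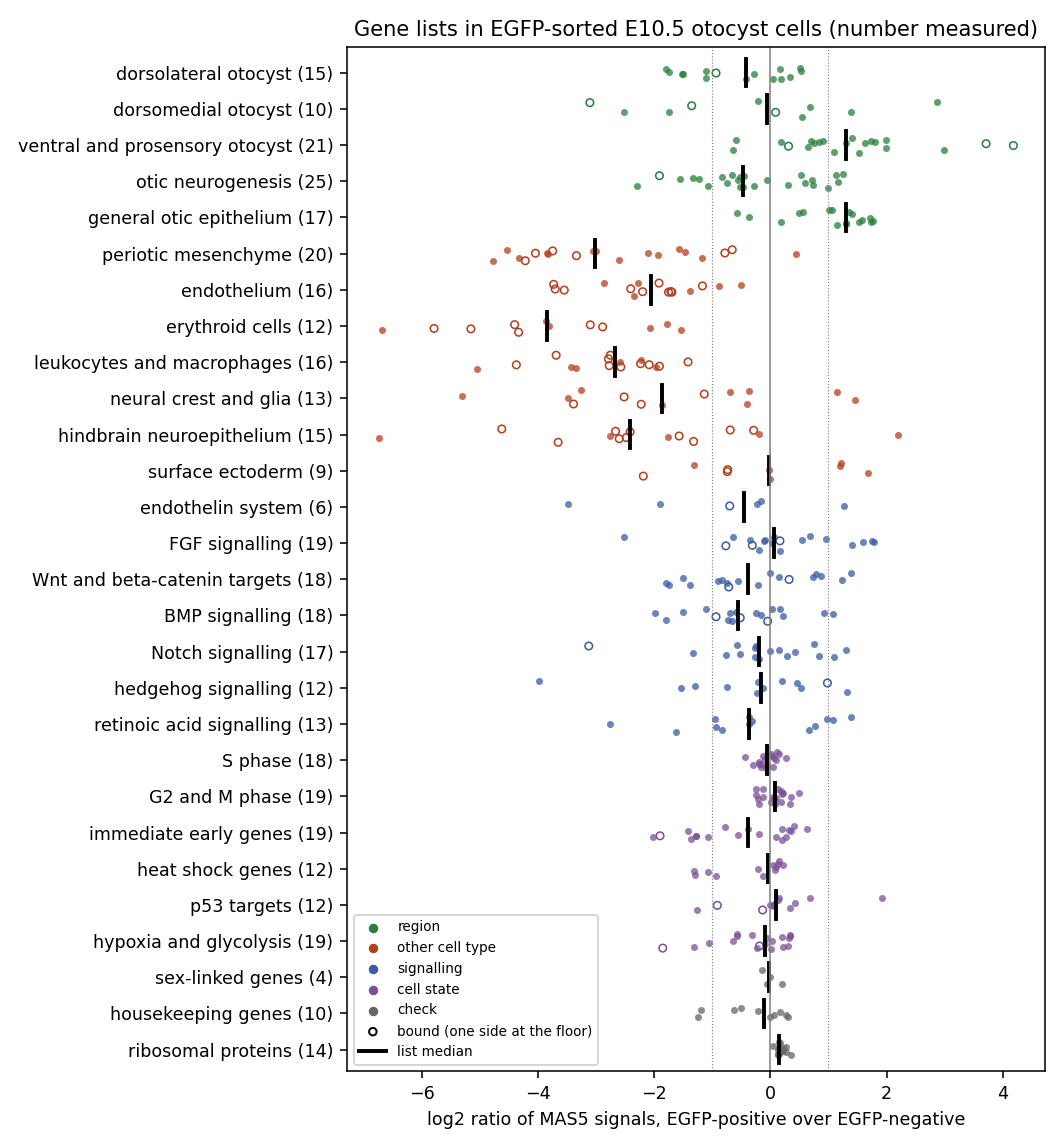
Log2 ratio of MAS5 signals, EGFP-positive over EGFP-negative (x axis), for every measured member of the 28 preset lists (y axis, number measured in brackets). Points are genes, open circles are bounds, black bars are list medians and dotted lines mark 2-fold. The medians of the blood, mesenchyme, endothelium, neural crest and hindbrain lists lie between -3.84 and -1.86.

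Signalling genes were examined as pathways. The BMP list had a median of -0.56 ± 0.22 (18 genes), below all random lists, with 4 members at least 2-fold higher in EGFP-negative cells and 1, Id4 (496.0 against 235.2, named after its values were seen), in EGFP-positive cells. The 4 included Bmper, which encodes an extracellular BMP modulator, 3.96-fold higher, besides Msx2, Bmp4 and Msx1, which the dorsolateral list also holds. The list of Wnt and beta-catenin targets stood at -0.39 ± 0.39 (18 genes, percentile 0.14), retinoic acid at -0.37 ± 0.52 (13 genes, percentile 0.94) and Notch at -0.20 ± 0.23 (17 genes, percentile 1.32). In the Wnt list 2 members were at least 2-fold higher in EGFP-positive and 4 in EGFP-negative cells, and in the Notch list 2 were in each. In the retinoic acid list, Crabp1 was 6.78-fold and Cyp26b1, which encodes a retinoic acid hydroxylase, 3.10-fold higher in EGFP-negative cells, whereas Aldh1a3 and Rdh10, which act in its synthesis, were 2.62-fold and 2.12-fold higher in EGFP-positive cells. With the floor at the 60th percentile, to which its EGFP-negative signal of 14.0 was raised, the log2 ratio of Aldh1a3 was -0.031. Its lowest probe set was at 0.34. The Notch target gene Hes5 had a signal of 90.9 in EGFP-negative against 3.7 in EGFP-positive cells. The Notch list stood apart in 4 of 9 other settings, the retinoic acid list in 7 and the BMP and Wnt lists in all 9. Markers of mesenchyme, with a median of -3.02, were higher in the same library as the genes that were low in these lists. The FGF list was at 0.06 ± 0.24 (19 genes), with 4 members at least 2-fold higher in EGFP-positive cells and 1, Fgfr3, in EGFP-negative cells. Among the 4 were Il17rd, a feedback inhibitor of FGF signalling, and Fgf9, 3.43-fold and 3.38-fold higher. Spry1, another feedback inhibitor, had a log2 ratio of 1.59. The second probe sets of Fgf9 and Il17rd were at 0.0082 and 0.98. The hedgehog list was at -0.17 ± 0.36 (12 genes), in which Gli1 was 2.49-fold higher in EGFP-positive cells and Shh, Boc and Foxd1 were 2.89-fold, 2.47-fold and 15.8-fold higher in EGFP-negative cells, though 1 of the 3 probe sets of Boc was at -0.16. The hedgehog list stood apart in 2 of 9 other settings.

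Of the endothelin genes, the receptor gene Ednrb was 11.3-fold higher in EGFP-negative cells, with all 3 probe sets between -3.49 and -2.45, and its ligand gene Edn3 was 3.74-fold higher. Ecel1 was 2.42-fold higher in EGFP-positive cells, but its log2 ratio was -0.047 with the floor at the 60th percentile. The list of 6 measured endothelin genes did not stand apart, with a median of -0.46 ± 0.77 at percentile 6.17, but did in 1 of 9 other settings. Of the 13 measured markers of neural crest, among which Ednrb was listed, 8 were at least 2-fold higher in EGFP-negative and 2 in EGFP-positive cells.

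Cell cycle genes were at similar levels. None of 18 S phase and 19 G2 and M phase genes differed by 2-fold, with medians of -0.07 ± 0.06 (percentile 0.51) and 0.07 ± 0.06, and the S phase list stood apart in 7 of 9 other settings. The largest ratios were those of Ccne2, 1.35-fold higher in EGFP-negative cells, and Kif20a, 1.40-fold higher in EGFP-positive cells. Immediate early genes had a median of -0.39 ± 0.41 (19 genes, percentile 0.175), with 7 at least 2-fold higher in EGFP-negative cells, among them Myc (4.07-fold), Klf2 (38.8 against 6.8), Zfp36 (2.67-fold) and Klf6 (2.57-fold). The least different probe set of Klf6 was at -0.48. This list stood apart in 7 of 9 other settings, and its median was -0.06 with the floor at the 60th percentile. Markers of leukocytes, with a median of -2.67, were higher in the same library. Heat shock genes stood at -0.04 ± 0.32, with Hspa1b and Hspb1 2.48-fold and 2.47-fold higher in EGFP-negative cells. The p53 target list was at 0.10 ± 0.12, but its member Cdkn1a, a cyclin-dependent kinase inhibitor gene, was 3.80-fold higher in EGFP-positive cells and its member Sesn1 2.41-fold higher in EGFP-negative cells, with its least different probe set at -0.88. Hypoxia and glycolysis genes were at -0.09 ± 0.16, with the glucose transporter gene Slc2a3 at 135.6 in EGFP-positive and 339.1 in EGFP-negative cells, and its least different probe set at a log2 ratio of -0.89. Ribosomal protein genes were at 0.16 ± 0.02 and housekeeping genes at -0.11 ± 0.27 (10 genes, percentile 1.06), of which Gusb and B2m were 2.37-fold and 2.28-fold higher in EGFP-negative cells. The housekeeping list, a preset check, thus stood apart, as it did in all 9 other settings. Of the 28 preset lists, 17 stood apart, so standing apart does not by itself set a pathway off from this check. The sex-linked genes Xist, Eif2s3y, Kdm5d and Uty had log2 ratios between -0.15 and 0.19.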

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

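The tests of scaling, of the dorsolateral list and of the ventral list were chosen only after their results were seen. The further marker, epithelial and arch lists were written down before their own values were seen, though after the preset lists had been examined.

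Markers of blood, leukocytes, endothelium, mesenchyme and hindbrain were higher in the EGFP-negative library, where Hbb-bh1 had a signal of 7047 against 500.5 and Hbb-y 6191 against 2121, so globin RNA was in both libraries (both genes were chosen after their values were seen). The median log2 ratio of all genes above the floor in both libraries was 0.031. Both arrays had been scaled to a common level, so this value cannot test a difference in scaling. The 12 hybridisation controls lay between 0.15 and 0.36. A single scaling factor would move all lists alike, whereas the further epithelial list was at 1.35 and the erythroid list at -3.84. These medians argue against scaling alone. RNA of other cell types is a candidate explanation, which required 5 further marker lists to have medians of -1 or lower. The highest of the 5 was that of hindbrain, -1.28 ± 0.46, so the limit of -1 lay within its error. These 5 lists mark the same cell types as the preset lists, so they restate the pattern and cannot tell its cause. A lower share of epithelium stays open too, with the further epithelial list at 1.35 ± 0.16, and may be another side of the same difference. The erythroid (-3.84 ± 0.59) and endothelial (-2.06 ± 0.28) medians lie apart, with 6 of 12 and 10 of 16 members as bounds. Their errors are spreads among list members and not between samples. This gap does not count against a lower share of epithelium, since each other cell type could have its own share. The labels call both fractions epithelial but name no gate besides EGFP. Expression of some of these marker genes in dorsolateral epithelium was not tested.

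Genes of the ventral otocyst were higher in EGFP-positive cells, and a lower share of epithelium in the EGFP-negative library alone may account for the list as a whole. Its median differed from that of the further epithelial list by -0.047 ± 0.32 on the log2 scale. Of its 21 members, 5 (Otx1, Otx2, Emx2, Bdnf and Tbx2) exceeded the highest of the 28 epithelial ratios, 1.82, as did 61 of 13362 genes (0.457%), and 2 lay below the lowest, Fgf3 at -0.65 and Prox1 at -0.60, both named after their values were seen. The claudin genes Cldn9 (2.24), Cldn10 (at least 2.44) and Cldn22 (2.85), picked after their ratios were seen, passed it too, and of the 5 genes Otx2 (at least 4.18), Otx1 (at least 3.72) and Emx2 (2.98) exceeded these as well, while the second probe set of Bdnf was at 0.88. A difference between the territories that the labels describe stays open for these 5, as untested, and 1 array per population leaves their error unknown.

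Of the 15 dorsolateral genes, 9 had ratios below the lowest epithelial ratio, and the other 6, Dlx5 and Dlx6 among them, lay within the epithelial range. The low end of that range, -0.008, was set by Elf3, with signals of 53.8 in EGFP-positive and 54.1 in EGFP-negative cells. Lying within the range therefore says little about a single gene. The list median differed from that of the further epithelial list by -1.76 ± 0.49, which argues against a lower share of epithelium alone for the list as a whole, but not for each of those 6. Several members, such as Msx1, Msx2, Bmp4 and Meis2, are also expressed in mesenchyme or neural tissue, so RNA of other cells could raise them. For Dlx5 and Dlx6 (the second chosen after its values were seen), branchial arch mesenchyme cannot be told apart, since 7 of its genes had a median of -0.34 ± 0.52. Among the 7, Hand1 (12.2 in EGFP-positive against 15.4 in EGFP-negative cells), Barx1 (11.3 against 17.9) and Alx4 (10.9 against 13.3) lay near the floor. Higher expression in dorsolateral epithelium, the territory that the labels describe as lacking EGFP, stays open and untested.

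Probe sets outside the comparisons also carried signal above the bacterial controls. Of 10092 probe sets that do not name 1 gene, controls apart, 4975 exceeded the highest of those controls in at least 1 library, and 66 were at least 2-fold higher in EGFP-positive cells and 196 in EGFP-negative cells. The control probe set for the 5' part of 18S ribosomal RNA had a log2 ratio of -1.84, with signals of 306.1 in EGFP-positive and 1095 in EGFP-negative cells, whereas those for its middle and 3' parts were at -0.11 and -0.49.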

How the results depend on the processing

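The floor at the 75th percentile and both centrings were added after seeing the data, and were applied only to the counts and to the dorsolateral, dorsomedial, ventral, neurogenesis and mesenchyme lists. No paired analysis was possible because each population has 1 array, and for the same reason no replicate could be left out. The 3 planned scalings kept both counts within 1.5 times of the 388 and 1019 genes. The count higher in EGFP-positive cells moved to 237 with the floor at the 60th percentile, 255 with a pseudocount, and 1047 and 104 with limits of 1.5-fold and 3-fold. The count higher in EGFP-negative cells moved to 1590 and 478 with the floor at the 25th and 60th percentile, 632 without bounds, and 1934 and 491 with limits of 1.5-fold and 3-fold. Of the medians of these 5 lists, 44 of 45 planned values lay within 1 bootstrap SD. Even so, the dorsomedial list, with its large SD, came to stand apart without bounds, at 0.54 and percentile 99.85. That setting leaves out Pax3 and Wnt3a for their low signal in EGFP-positive cells, which itself moves the median up. The value beyond 1 SD was mesenchyme at -2.24 with the floor at the 60th percentile, where more members reach the floor. For the other lists 22 values moved by more than 1 SD, with medians reaching 1.05 (general otic epithelium), -2.69 (erythroid), -1.11 (leukocytes), -1.02 (endothelium), -0.99 (hindbrain) and -0.69 (neural crest), and each of these lists stayed apart in all 9 settings. Of lists that did not stand apart, surface ectoderm and hedgehog did in 2 of the 9 settings and endothelin and heat shock in 1. The S phase median turned from -0.07 to 0.0067 without _s_at and _x_at probe sets, and the log2 ratios of Aldh1a3 and Ecel1 to -0.031 and -0.047 with the floor at the 60th percentile, where the cause was not tested. A floor at the 75th percentile gave 127 and 165 genes, a ventral median of 0.90 and a mesenchyme median of -1.65. Centring on the 12 hybridisation controls, which lay at 0.25, gave 225 and 1442 genes. Centring on the further epithelial list lowered every ratio by 1.35, which gave 19 and 10706 genes and medians of -1.76 (dorsolateral), -1.41 (dorsomedial), -0.047 (ventral), -1.82 (neurogenesis) and -4.38 (mesenchyme). Under this centring any gene less than 2.55-fold higher in EGFP-positive cells turns direction. These last 2 shifts moved the median of all genes from 0.03 to -0.22 and -1.32, and the planned scalings moved it by less than 0.1. Signal near the floor limits the largest ratios, since 387 of the 1019 genes higher in EGFP-negative cells are bounds.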

Other observations

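The gene families, formed by the start of the gene symbol, and the 5 hair bundle genes named first were chosen after their values were seen. So was the test on all 16 genes listed for the hair bundle, whereas the test on 11 further ones was written before. All 4 measured Zic genes were at least 2-fold higher in EGFP-negative cells, with Zic5 at 206.5 against 3.1. Of 11 measured Hox genes, which mark position along the hindbrain and trunk, 7 were at least 2-fold higher in EGFP-negative cells and none in EGFP-positive cells, with Hoxa5 and Hoxc6 at log2 ratios of 0.35 and 0.12. The second probe sets of Hoxa5 and Hoxc6 went the other way, at -0.29 and -0.96. Hoxb3 had 256.8 in EGFP-negative against 4.1 in EGFP-positive cells and Hoxa2 131.0 against 7.3. Of 33 collagen genes, 12 were at least 2-fold higher in EGFP-negative cells and 2 (Col6a1 and Col9a2) in EGFP-positive cells. Col2a1 had a signal of 2036 in EGFP-positive and 1087 in EGFP-negative cells, and Col11a1 had 221.7 and 333.7. Of 9 laminin genes, 4 were at least 2-fold higher in EGFP-negative cells, with Lama4 at 87.8 against 5.5 and its second probe set at a log2 ratio of -0.93, and Lama5 was 2.02-fold higher in EGFP-positive cells. Markers of hindbrain, mesenchyme and endothelium, with medians of -2.42, -3.02 and -2.06, were also higher in EGFP-negative cells. The hindbrain list holds some of these Hox and Zic genes, and the mesenchyme list some of the collagen genes.

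Of 17 measured claudins, the barrier proteins of tight junctions, 7 were at least 2-fold higher in EGFP-positive cells, with Cldn9 at 1114 against 236.1, and 3 in EGFP-negative cells, among them the endothelial Cldn5, while the other 7 were within 2-fold. Genes of epithelium were higher in EGFP-positive cells too, with the further epithelial list at 1.35, and the epithelial lists hold several of these claudins. Of 5 Irx homeobox genes, 3 were at least 2-fold higher in EGFP-positive cells. Irx3 had a signal of 1700 against 372.4 and Irx5 448.2 against 162.4, whereas Irx1 and Irx2 had log2 ratios of -0.47 and 0.11. Irx3 had been placed in the hindbrain list, where it was the only member at least 2-fold higher in EGFP-positive cells.

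Some genes of the hair bundle, the mechanosensory organelle of hair cells, had high ratios in EGFP-positive cells although hair cells form later in development. Espn was 6.89-fold, Pls1 4.99-fold, Calml4 at least 4.82-fold, Clrn1 at least 4.74-fold and Pcdh15 at least 3.15-fold higher. The lower signal of Espn, 13.3, was next to the floor. A hypothesis that hair bundle genes as a group are higher beyond the epithelial difference was tested on 11 measured genes of a list whose values had not been seen. Their median was 0.31, at percentile 98.6 of random lists, and differed from that of the further epithelial list by -1.04 ± 0.20 on the log2 scale. With the 5 genes above included, the median of the 16 was 0.47, a difference of -0.88 ± 0.49. Both values go against a rise of the group beyond that of epithelium, while the 5 genes taken singly stay open, and several of the 11 lie near the floor. Of the 11, Myo7a was higher in EGFP-positive cells (296.3 against 77.2) and Atoh1 in EGFP-negative cells (73.5 against 4.6), while the other 9 were within 2-fold. Atoh1 encodes a transcription factor and not a part of the bundle, though the list holds it. Markers of hindbrain, with a median of -2.42, were higher in the same library as Atoh1.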
